A study of Glycine max with 10 samples.

How the data were processed

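Transcript abundance was measured on 10 Affymetrix soybean gene arrays, each hybridised with biotinylated cRNA made from total RNA of a separate plant. The plants were Glycine max, grown in a greenhouse and sampled at 6 weeks, and the above-ground part was taken. The labels give 4 wild type plants and, among plants carrying an RNA interference construct against MSH1, 3 with variegated and 3 with stunted growth. MSH1 is a nuclear gene whose product acts in mitochondria and plastids, where it limits recombination between repeats of the organelle genomes.

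The deposited values are log2 probe set summaries. Per the labels, the authors made them with RMA in the affy package, which corrects background, equalises the distribution of the arrays and combines the probes of a probe set. The versions, the probe set definitions used and any filter applied are not given in the sources used here. The values carry no count or depth, so the number of arrays limits the precision. The table holds 61170 probe sets in 10 columns, and no value column was left unused. Of these, 37593 are soybean probe sets, 15820 were designed on the oomycete Phytophthora sojae, 7530 on the nematode Heterodera glycines, and 227 are other controls.

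The 23350 probe sets of the 2 pathogens served as a measure of background. A soybean probe set was tested when it exceeded the 95th percentile of the pathogen probe sets of an array, which lay between 3.77 and 3.97, on at least 3 of the 10 arrays. That kept 30981 probe sets and left out 6612. In the text, at background means below that percentile on every array of the group named. Where a group was at background, a fold is given as a lower limit computed from the percentile.

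Gene symbols came from a table that gives genes for 9047 of the probe sets, updated through the gene ID in a RefSeq table for 8652 of the 8677 with a single gene. The other 25 kept the older symbol. Among the probe sets tested, 7812 had a single gene, 343 had several and 22826 had none. Of the single-gene probe sets tested, 1594 carried a name other than a locus number, over 992 genes. The tables used held no gene descriptions, so list patterns and the rule for names were matched to symbols and synonyms. The arrays and tables used name no shared genome build, and no coordinates are given.

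Fold changes and tests came from limma 3.58.1 in R 4.3.3. A linear model with a mean for each of the 3 groups was fitted to all 10 arrays, the 3 differences between groups were taken as contrasts, and eBayes moderated the variances (7 residual and 3.04 prior degrees of freedom). A probe set was called when its Benjamini-Hochberg adjusted p within the contrast was under 0.05, and rose or fell by the sign of the contrast. Changes and differences not written as a fold are on the log2 scale. Standard errors (SE) are those of the moderated fit. Group values are given as mean ± SD of the arrays.

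The method was tested on data simulated once, with the real means and spreads and independent noise. In each comparison 67, 67 and 66 of 30981 probe sets were changed 1.5-fold, 2-fold and 4-fold. Of probe sets changed 2-fold, 79.1% were recovered in variegated against wild type, 79.1% in stunted against wild type and 80.6% in stunted against variegated. At 1.5-fold the shares were 53.7%, 46.3% and 29.9%. False calls made up 1.90%, 3.87% and 9.15% of the calls. Far more probe sets were called in the real comparisons with stunted plants, so these shares need not hold there.

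Gene lists were tested with camera in limma, which compares the members of a list with all other genes, at a preset correlation of 0.01 between genes and again with the correlation estimated for each list. They were also tested with fry, which asks whether the members move on balance in a single direction and makes no comparison with other genes. Each gene was represented by its probe set with the highest mean over the arrays. Of 31 lists fixed before the data were examined, 8 had at least 5 genes tested. A further 21 lists, built from gene symbols after the symbols and the correlations of the arrays had been seen and before any groups were compared, added 19. The p values were adjusted over all 81 combinations of list and comparison. For lists fixed beforehand, members were also counted with p adjusted over the list alone. In the text, lists of the second kind are called lists by symbol.

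The genes named were chosen by a rule set before the data were examined. It takes MSH1 in every array. It then takes, for each comparison, the 12 largest rises and 12 largest falls among called probe sets of a single named gene whose 2 groups of arrays did not overlap, with 1 probe set per gene. It adds up to 2 rises and 2 falls in each list, and up to 2 rises and 2 falls among probe sets without a gene. In variegated against wild type 11 falls met the rule. Genes outside it are said to have been chosen after their values were seen.

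Calls shared by the 2 RNA interference classes were counted by direction, since both comparisons use the same wild type arrays. The count was set beside the overlap of independent lists, beside 100 simulations in which neither class differed from wild type, and beside the 6 ways of giving each class a separate pair of the wild type arrays.

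Alternatives set before the data were examined were no filter, a stricter filter (a mean of at least 4.48), cyclic loess, scaling to the median of the pathogen probe sets, eBayes with trend and robust, array weights, a model of only the groups compared, the replicate number as a block, a fold change of at least 2, an adjusted p under 0.01, 1 probe set per gene, all probe sets per gene, an estimated correlation, and leaving out each array in turn. Alternatives chosen after the data were seen were a covariate for a score of ribosomal RNA probe sets, leaving out the 3 arrays low on that score, and a covariate for the actin 3' minus 5' signal. The score is the mean log2 signal of reverse-strand minus forward-strand soybean ribosomal RNA control probe sets. Permutation tests of single values are exact and two-sided.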

Results

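The data are 10 arrays of the above-ground part of 6-week-old soybean plants: 4 wild type, 3 variegated and 3 stunted plants, the last 2 groups carrying an RNA interference construct against MSH1. RNA was extracted from each plant, so the arrays of a group are separate plants. The median soybean probe set stood between 6.59 and 6.68 on the log2 scale on the 10 arrays. Between 78.7% and 81.4% of soybean probe sets exceeded the background level of their array. Arrays of the same group correlated across probe sets at r between 0.975 and 0.989 in wild type, 0.990 and 0.994 in variegated and 0.981 and 0.990 in stunted plants. Stunted and wild type arrays correlated at 0.869 to 0.95. These correlations are across probe sets, which are not independent replicates. The first principal component held 71.2% of the variance and set the stunted arrays apart from all others. The second held 8.72% and separated wild type from variegated arrays.

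MSH1, the gene targeted by the construct, was lower in both classes of RNA interference plants. Its probe set above background read 5.41, 5.72, 5.36 and 5.11 on the wild type arrays, 4.73, 4.55 and 4.58 on the variegated arrays and 4.57, 4.48 and 4.07 on the stunted arrays. The means were 5.40 ± 0.25 (SD, n = 4), 4.62 ± 0.10 (n = 3) and 4.38 ± 0.27 (n = 3). On the log2 scale, which holds below for every change not written as a fold, MSH1 fell in both classes. It fell by 0.78 (SE 0.16, limma adjusted p = 0.0344) in variegated and by 1.02 (SE 0.16, adjusted p = 0.000539) in stunted plants. The 2 classes differed by -0.25 (adjusted p = 0.263). The variegated call was lost without wild type array 1, 2 or 3, any variegated array or stunted array 2, and with the ribosomal RNA covariate, with adjusted p up to 0.147. A second MSH1 probe set was at background in all groups.

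**Figure D1:**
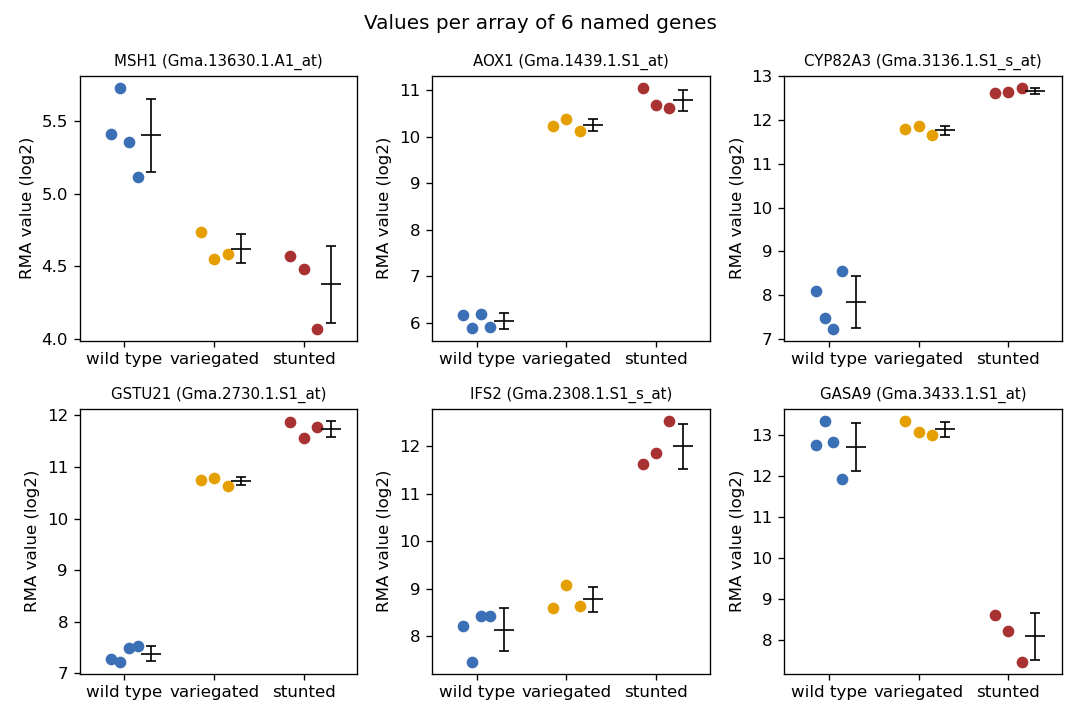
Log2 RMA values of 6 named genes on each array of wild type (n = 4), variegated (n = 3) and stunted (n = 3) plants; points are arrays, and the line with bars beside them is the mean ± SD. AOX1, CYP82A3 and GSTU21 were higher on every variegated and stunted array than on any wild type array, IFS2 was higher and GASA9 lower on every stunted array than on any other, and every MSH1 value of the RNA interference plants lay below every wild type value.

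The comparison of variegated with wild type plants asks which transcripts differ in RNA interference plants with variegated growth. AOX1, which encodes an alternative oxidase of mitochondria, had the largest rise of any named gene. Its brighter probe set went from 6.04 in wild type to 10.24 in variegated plants, a rise of 4.21 (SE 0.13, adjusted p = 1.30e-07). Its other probe set was at background in wild type and at least 11.4-fold higher in variegated plants. The cytochrome P450 gene CYP82A3 rose by 3.92 (SE 0.26, adjusted p = 4.77e-05), and the glutathione transferase genes GSTU21 and GSTU42 rose by 3.35 (adjusted p = 1.34e-07) and 2.02 (adjusted p = 0.00101). Each of these was higher on all 3 variegated arrays than on all 4 wild type arrays.

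The other named rises in variegated plants were smaller. NOD33 rose by 1.62 (adjusted p = 0.00147), the small heat shock protein gene HSP23.9 by 1.55 (adjusted p = 0.0322) and the vegetative storage protein gene VSP27 by 1.13 (adjusted p = 0.0126). SMEP1, which encodes a metalloproteinase, and the beta-amylase gene BMY1 each rose by 1.05, and the transcription factor genes BZIP105, WRKY19 and MYB138 by 0.99, 0.89 and 0.80. The falls were at most 1.16 in size. SC-03 fell by 1.16 (SE 0.16, adjusted p = 0.00549), the gibberellin-responsive peptide gene GASA11 by 0.90 (adjusted p = 0.0413), MYB177 by 0.88 and the sucrose transporter gene SUT1 by 0.75. IF7GT, an isoflavone glucosyltransferase gene, fell by 0.66, and GER10, PHR18, BCH3 and CYP26 fell by 0.54, 0.47, 0.39 and 0.36. WRKY15 fell to background in variegated and stunted plants and was at least 1.12-fold lower in each. Among probe sets without a gene, the rule named rises of 5.47 and 4.51, a fall of -1.53, and a probe set at background in variegated plants that was at least 1.29-fold lower.

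By gene list, at most 3 members of each list that camera called in variegated plants passed limma's threshold. Of 29 glutathione S-transferase genes, 3 rose (GSTU21, GSTU42 and GST24) and none fell, and 3 rose and 1 fell with p adjusted over the list alone. The median was 0.08 (camera adjusted p = 0.00551, adjusted p = 0.392 with an estimated correlation). Of 8 genes for jasmonate synthesis, lipoxygenases and vegetative storage proteins, VSP27 and VSPA rose, by 1.13 and 0.52, and the same 2 when adjusted over the list alone. Their probe sets disagreed: 1 of 3 for VSP27 rose (range 0.14 to 1.13) and 2 of 6 for VSPA (range -0.42 to 0.52), and 1 of those 6 fell in stunted plants. Their median was 0.23 (adjusted p = 0.000261, and adjusted p = 0.272 with an estimated correlation). The list of pathogenesis-related and defence proteins holds 51 genes, 48 of them WRKY transcription factors. WRKY19 and WRKY57 rose and WRKY15 fell, and 6 rose and 1 fell when adjusted over the list alone; the median was 0.15 (adjusted p = 0.00213, and adjusted p = 0.505 with an estimated correlation). The 47 WRKY genes of the list by symbol gave the same 3 calls, at a median of 0.14 (adjusted p = 0.00412, and adjusted p = 0.497 with an estimated correlation). For these 4 lists, in the order given, fry gave adjusted p of 0.011, 0.00797, 0.247 and 0.220, so it called the first 2 of them. No member of the ethylene (5 genes), antioxidant enzyme (5) or phenylpropanoid (5) lists fixed beforehand passed limma's threshold, over all probe sets or adjusted over the list alone, and fry gave adjusted p of 0.962, 0.976 and 0.360.

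In total 682 of 30981 probe sets (2.20%) were called in variegated plants, 512 rose and 170 fell, and 197 changed at least 2-fold (184 rose, 13 fell). At an unadjusted p under 0.05 there were 5096. Of these calls, 192 were of probe sets with a single gene. With each of the 5622 genes represented by its probe set with the highest mean, 111 genes rose and 29 fell. The count was 305 with the replicate number as a block, 430 with only the groups compared and 1040 with array weights. It was 450 without wild type array 2, 416 without stunted array 2, and 245, 195 and 225 without variegated arrays 1, 2 and 3. AOX1, CYP82A3, GSTU21, GSTU42, NOD33 and SC-03 kept their calls in every alternative tried on named genes, while the other genes named here lost theirs in at least 1.

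**Figure D2:**
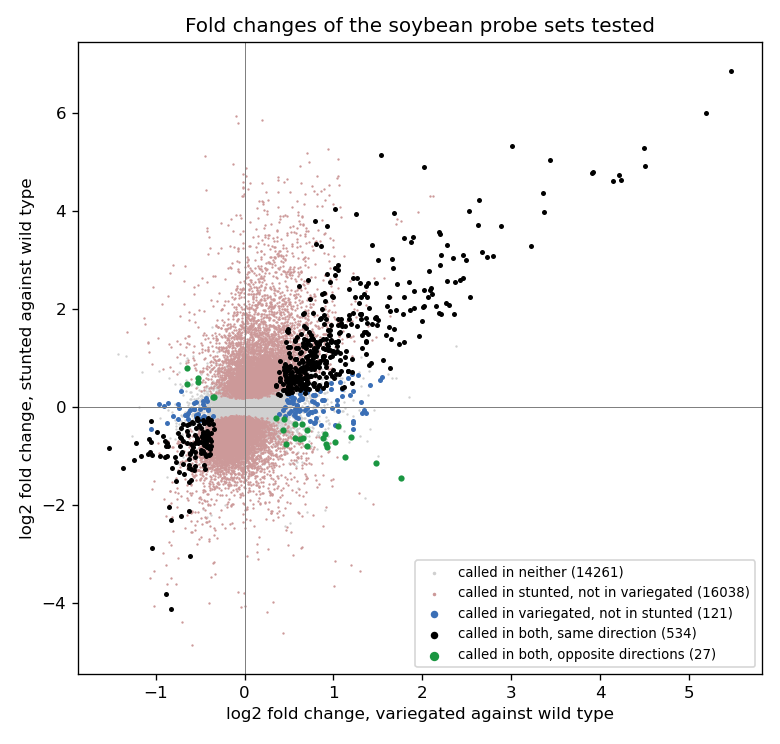
Log2 fold change against wild type of each soybean probe set tested in variegated (horizontal axis) and stunted (vertical axis) plants, coloured by the calls. Of the 682 probe sets called in variegated plants, 534 were called in the same direction in stunted plants (black) and 27 in the opposite direction (green).

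The comparison of stunted with wild type plants asks which transcripts differ in the RNA interference plants with reduced growth. Most of the phenylpropanoid and flavonoid genes, WRKY and NAC factors and glutathione S-transferases tested rose, as did AOX1 and CYP82A3, which also rose in variegated plants. AOX1 rose by 4.75 (SE 0.13, adjusted p = 3.14e-08) on its brighter probe set and was at least 20.1-fold higher on the other. GSTU42 rose by 4.91 (adjusted p = 5.53e-07), CYP82A3 by 4.81 (adjusted p = 2.52e-06) and GSTU21 by 4.36 (adjusted p = 1.61e-08). MYB92, at background in wild type on one of its probe sets, was at least 21.7-fold higher on that probe set (adjusted p = 4.59e-06). All 3 of its probe sets rose, the least by 0.58. OLPa, which encodes an osmotin-like protein, rose by 4.88 (SE 0.51, adjusted p = 7.45e-05), PTS-L4 by 4.67, CYP71D8 by 4.54 and the Bowman-Birk protease inhibitor gene BBI-1 by 3.84.

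Most phenylpropanoid and flavonoid genes rose and some fell. The isoflavone reductase gene IFR rose by 4.21 (SE 0.30, adjusted p = 1.08e-05), the isoflavone synthase gene IFS2 by 3.87 (adjusted p = 1.02e-05) and the chalcone synthase genes CHS1 and CHS8 by 3.85 and 3.24. All 5 genes of the list fixed beforehand (CHS1, CHS8, IFS1, IFS2 and PAL2.1) rose, over all probe sets and when adjusted over the list alone, at a median of 3.18 (adjusted p = 0.000909, and adjusted p = 0.372 with an estimated correlation). Of the 36 genes of the list by symbol, 26 rose and 5 fell at a median of 1.06 (adjusted p = 4.98e-06, and adjusted p = 0.329 with an estimated correlation). The 5 that fell were F3H, FLS1, ANS2, CHI3A1 and DFR2. On the log2 scale F3H fell by 1.54 (adjusted p = 0.000145), FLS1 by 1.43, ANS2 by 1.35 and CHI3A1 by 1.28, the last 3 chosen after their values were seen. DFR2 was at background in stunted plants and at least 1.87-fold lower (adjusted p = 3.22e-05), a lower limit that is not on the log2 scale. F3H, FLS1, DFR2 and ANS2 encode enzymes of flavonol and anthocyanin synthesis. CHS1 is read by several probe sets, and the brightest of them rose by 1.41.

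**Figure D3:**
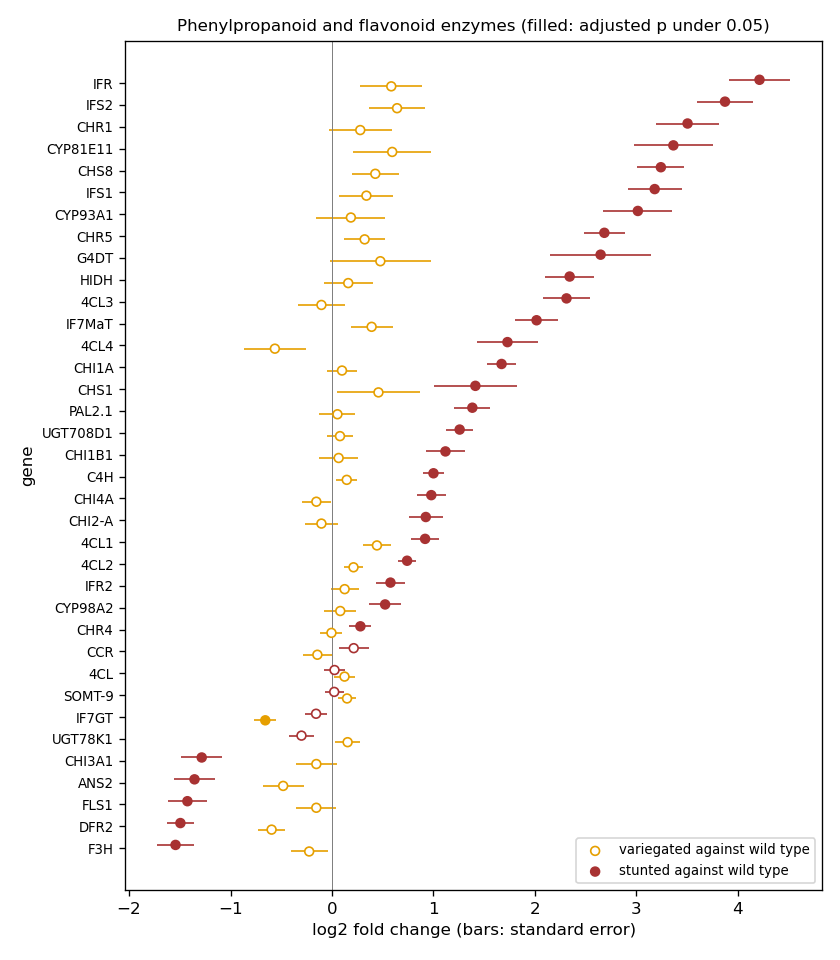
Log2 fold change against wild type of the 36 phenylpropanoid and flavonoid genes of the list by symbol, in variegated and stunted plants; bars are standard errors, filled points were called, and values are fitted ones, also for DFR2, at background in stunted plants. In stunted plants 26 rose and 5 fell, F3H, DFR2, FLS1, ANS2 and CHI3A1; in variegated plants IF7GT alone was called.

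Most members of several lists of defence genes and regulators rose in stunted plants. The 51 pathogenesis-related and defence genes are mostly WRKY factors, so this list and the WRKY list by symbol are not separate evidence. Of the 51, 38 rose and 1 fell, and 38 rose and 2 fell when adjusted over the list alone. Their median was 1.11 (adjusted p = 3.85e-11, and adjusted p = 0.272 with an estimated correlation), or 1.06 with values below background set to its level. PR1-7 rose by 3.43 (adjusted p = 1.75e-05) and PR-10 by 3.39 (adjusted p = 4.02e-05). Of the 47 WRKY genes by symbol, 34 rose and WRKY15 fell. WRKY62 and WRKY63, at background in wild type, were at least 5.71-fold and 7.31-fold higher. The median was 1.01 (adjusted p = 6.93e-10, and adjusted p = 0.272 with an estimated correlation). Of 14 NAC transcription factor genes, 13 rose, NAC26 by 3.05 and NAC1 by 2.84, and none fell, at a median of 1.33 (adjusted p = 9.07e-05, and adjusted p = 0.272 with an estimated correlation). The list by symbol of pathogenesis-related and resistance genes had 13 of 21 rise, among them the chitinase gene CHIA1 by 3.52, and EDS5 fall, at a median of 0.82 (adjusted p = 0.000243, and adjusted p = 0.272 with an estimated correlation). Of 5 ethylene genes 4 rose, ERF5 by 1.41 and ERF6 by 1.04, and all 5 when adjusted over the list alone. Their median was 0.53 (adjusted p = 0.0197, and adjusted p = 0.272 with an estimated correlation). Of 54 bZIP factor genes 21 rose and 8 fell at a median of 0.14 (adjusted p = 0.0115, and adjusted p = 0.272 with an estimated correlation).

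Most glutathione S-transferases rose and some fell. Of the 29 genes fixed beforehand, 17 rose and 3 fell, and 19 rose and 3 fell when adjusted over the list alone. The median was 0.59 (adjusted p = 0.000397, and adjusted p = 0.329 with an estimated correlation). GSTU42 and GSTU21 led the rises, and GmGSTU2 and GSTU3 fell by 1.70 (adjusted p = 0.000289) and 1.56. The 22 genes of the list by symbol gave 15 rises and 1 fall at a median of 0.65 (adjusted p = 0.000397, and adjusted p = 0.372 with an estimated correlation). GSTU47 is read by 4 probe sets, of which 2 rose and 2 fell. Of the 3 alternative oxidase genes tested, AOX1 and AOX3 rose, the latter by 1.65 (adjusted p = 4.95e-05), and AOX2 fell by 0.38 (adjusted p = 0.00759).

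Most GASA genes tested fell in stunted plants. GASA9, of the gibberellin-responsive GASA peptide family, had the largest fall among the genes the rule named, by 4.61 (SE 0.32, adjusted p = 9.90e-06), from 12.71 ± 0.58 (SD, n = 4) to 8.10 ± 0.57 (n = 3). Of 15 GASA genes 10 fell, GASA6 by 1.75 (adjusted p = 0.000114), and GASA14 rose by 0.36; the median was -0.70 (adjusted p = 0.0336, and adjusted p = 0.272 with an estimated correlation). The wider gibberellin list fixed beforehand had 11 of 18 genes fall and 2 rise, and 12 fall and 2 rise when adjusted over the list alone. Its median was -0.58 (adjusted p = 0.0907), so the list was not called. AS2 fell by 4.08 (adjusted p = 2.17e-05), the fatty acid desaturase gene FAD3C by 2.55, MYB121 by 2.29 and AP1A by 2.16. The MADS-box gene NMH7, the annexin gene ANN11 and the heat shock factor gene HSF-08 fell to background in stunted plants and were at least 3.00-fold, 1.96-fold and 2.07-fold lower. SIP1-6, ENOD55-2, the nitrate reductase gene INR1 and the sugar transporter gene SWEET17 fell by 2.15, 2.14, 2.03 and 1.98. Of 36 photosynthesis and plastid genes by symbol, 19 fell and 5 rose at a median of -0.27 (adjusted p = 0.0432, and adjusted p = 0.610 with an estimated correlation). The 4 reference genes, too few for a list test, had a median of -0.39, so a fall of that size was not particular to photosynthesis genes. ELIP, which encodes an early light-induced protein, fell by 1.20 and HPT1 by 1.25, while SGR1 and SGR2, which act in chlorophyll breakdown, rose by 0.94 and 0.97. The photosynthesis list was not called under cyclic loess (median -0.13), with array weights, or without wild type array 3, stunted array 1 or stunted array 3. The GASA list was not called with all probe sets per gene (median -0.47), and the gibberellin list was called under cyclic loess (median -0.49).

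The few markers of other tissues tested did not move in a single direction. The lists for flower and pollen, meristem and young leaf, and secondary wall held no gene, since their patterns matched no symbol or synonym. Genes of these tissues may have been measured under other names. The root and nodule marker tested gave 0.31 (adjusted p = 0.213) and the seed markers KTI-2 and KTI-3 gave 0.02 (adjusted p = 0.939) and -0.25 (adjusted p = 0.229). Bowman-Birk inhibitors were meant for the seed list, but its pattern did not match the symbol BBI-1. That gene rose by 2.97 and 3.84 on its 2 probe sets. By symbol, the nodule protein genes NOD33, N-36A and ENOD40B rose by 2.24, 0.67 and 0.73 and ENOD55-2 fell. Among reference genes, an actin gene fell by 0.51 (adjusted p = 0.00106) and TUBB3 by 0.43, and both fell under cyclic loess and under scaling to the pathogen probe sets too. The control probe sets for the 3' and 5' ends of the main actin transcript differed by more on every stunted array than on every wild type array (1.13 ± 0.17 against 0.82 ± 0.17, SD, n = 3 and 4; exact two-sided permutation p = 0.0286, the smallest this design allows). For a glutathione transferase control the difference was smaller in stunted plants, by -0.31 (exact permutation p = 0.0571).

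In total 16599 of 30981 probe sets (53.6%) were called in stunted plants, 7535 rose and 9064 fell, and 3510 changed at least 2-fold (2334 rose, 1176 fell). With each of the 5622 genes tested represented by its probe set with the highest mean, 1349 rose and 1917 fell. Falls did not outnumber rises under cyclic loess (8640 rose, 7834 fell) or under scaling to the pathogen probe sets (8068 rose, 7751 fell). Without any single array the count stayed between 12694 and 17032. Of 107 named results, 9 lost their call without stunted array 3, 6 without stunted array 2, and at most 3 without any other array. They included WRKY15 (wild type array 1 or 2 or stunted array 3, adjusted p up to 0.0912), EDS5 (stunted array 3, up to 0.0630) and GASA14 (stunted array 2 or 3, up to 0.0600); WRKY15 was also lost under scaling to the pathogen probe sets. Among probe sets without a gene, the rule named a rise of 6.86 and a probe set at background in wild type that was at least 21.5-fold higher, and 2 probe sets at background in stunted plants that were at least 8.64-fold and 16-fold lower.

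**Figure D4:**
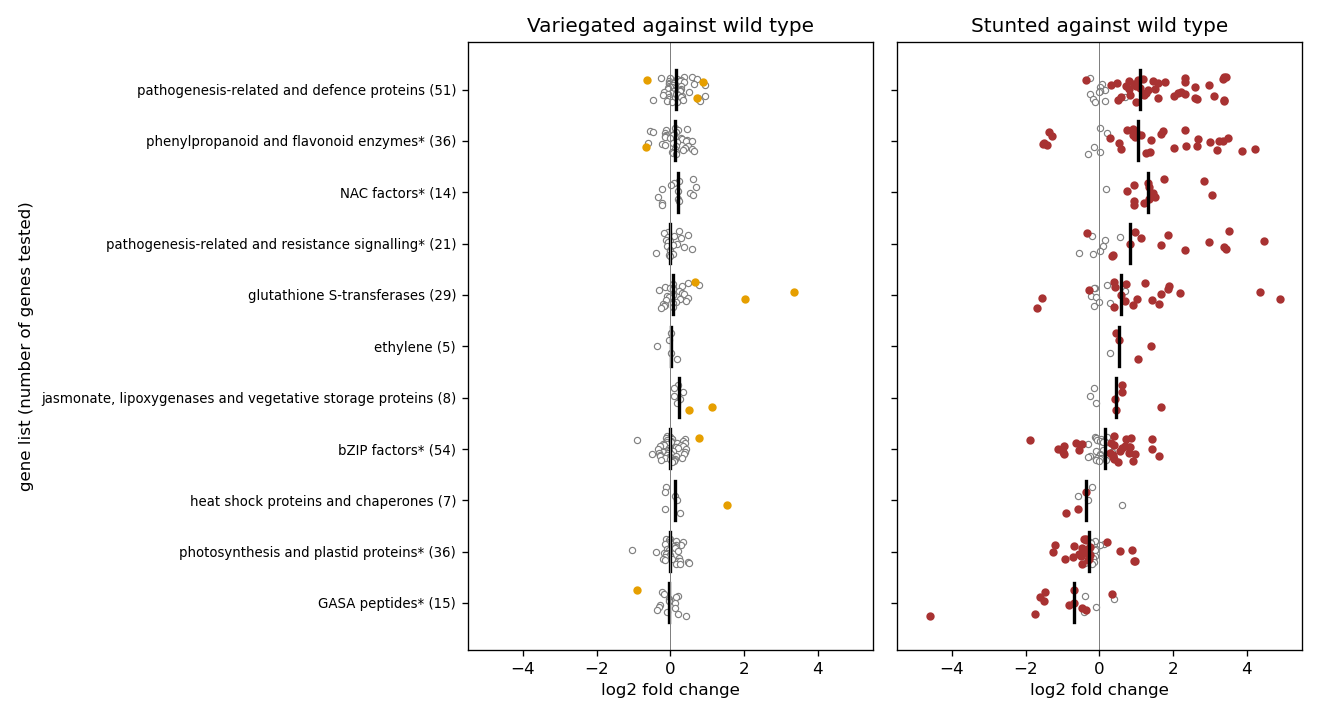
Log2 fold change against wild type of every member of 11 gene lists in variegated (left) and stunted (right) plants; points are fitted values of genes, also where a group is at background, filled where called, black lines are list medians, and an asterisk marks lists by symbol. In stunted plants the medians were 1.11 for pathogenesis-related and defence genes (mostly WRKY factors), 1.33 for NAC factors and -0.70 for GASA peptides. In variegated plants they were 0.15, 0.21 and -0.05.

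Changes shared by the 2 classes were counted because both are compared with the same wild type plants. AOX1, CYP82A3, GSTU21, GSTU42, NOD33, VSP27, SMEP1, BZIP105 and WRKY19 rose in both, and SC-03, GASA11, MYB177, SUT1, GER10, PHR18, BCH3 and CYP26 fell in both with MSH1. Many of the calls in variegated plants were weak. Of 18 alternatives, BCH3 lost its call in 16 (adjusted p up to 0.187), CYP26 in 14, PHR18 in 13, GASA11 in 11, WRKY19 and MSH1 in 8 each, and MYB177 and GER10 in 6 each. Only 1 of 3 probe sets of BCH3 was called there (range -0.39 to -0.02), and 1 of 3 of WRKY19. Of the 682 probe sets called in variegated plants, 534 (78.3%) were called in the same direction in stunted plants, 407 up and 127 down. Independent lists would share 124.5 upward and 49.7 downward. Fold changes of the 2 comparisons correlated across probe sets at 0.481, beside 0.429 in 100 simulations with the same shared wild type arrays and no difference in either class, and their covariance was 0.107 beside 0.0113. With a separate pair of wild type arrays for each class, 178 to 861 probe sets were shared, 3 to 195 were called in opposite directions, r was 0.113 to 0.568 and the covariance was 0.0306 to 0.127 over the 6 ways. With wild type arrays 1 and 4 for variegated and 2 and 3 for stunted plants, 369 were shared and 195 opposite. The shared count was 341 without wild type array 2, 335 without stunted array 2, and 221, 167 and 194 without variegated arrays 1, 2 and 3.

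The direct comparison of stunted with variegated plants tests which changes differ between the classes. Among genes the rule named, those higher in stunted plants were OLPa by 4.86 (SE 0.55, adjusted p = 0.000261), PTS-L4 by 4.19, MYB92 by 4.01, BBI-1 by 3.99, IFR by 3.63 (adjusted p = 0.000106), CYP71D8 by 3.48, CHS1 by 3.44, the chalcone reductase gene CHR1 by 3.43, CHIA1 by 3.29, and IFS2, GmIFR and CYP93A2 by 3.23, 3.23 and 3.20. GASA9 stood lower by -5.04 (adjusted p = 4.69e-05), AS2 by -4.04, SWEET17 by -2.65, PDH by -2.42, MYB121 by -2.30, the xyloglucan endotransglycosylase gene XET1 by -2.27, OAS-TL6 by -2.20, GSTU47 by -2.16, INR1 by -2.06 and GSTU3 by -2.03. HSF-08 and NMH7, at background in stunted plants, were at least 2.54-fold and 2.41-fold lower. For some genes above, other probe sets gave less. The ranges were 0.74 to 4.01 for MYB92, 0.96 to 3.44 for CHS1, -2.42 to -0.64 for PDH and -2.16 to 0.27 for GSTU47. Not called were 1 of 5 probe sets for CHS1, 1 of 3 for PDH and 2 of 4 for GSTU47. The genes that rose most in variegated plants were higher still in stunted plants, by 0.54 for AOX1 (adjusted p = 0.0125), 0.89 for CYP82A3 (adjusted p = 0.0294), 1.01 for GSTU21 (adjusted p = 0.000257) and 2.89 for GSTU42 (adjusted p = 5.97e-05).

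Some genes were raised or lowered in variegated plants and differed from stunted plants. BMY1 was lower in stunted than in variegated plants by -1.13 (adjusted p = 0.00167), MYB138 by -0.89 (adjusted p = 0.00393) and HSP23.9 by -0.93 (adjusted p = 0.0427), and against wild type the stunted values were -0.08, -0.09 and 0.61 (adjusted p = 0.723, 0.670 and 0.111). IF7GT was higher by 0.50 (adjusted p = 0.00785), and gave -0.16 (adjusted p = 0.244) in stunted against wild type. Each of these genes lost its call in variegated against wild type plants in at least 1 alternative. The HSP23.9 difference was lost under cyclic loess, with the ribosomal RNA covariate and without any variegated array, wild type array 1 or 3, or stunted array 2 or 3, with adjusted p up to 0.156.

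By list, stunted exceeded variegated plants in 35 of 51 pathogenesis-related and defence genes, mostly WRKY factors, with 1 lower. The counts were the same when adjusted over the list alone (median 0.98, adjusted p = 1.58e-11, and adjusted p = 0.272 with an estimated correlation). Of the 5 phenylpropanoid genes fixed beforehand 4 were higher, also when adjusted over the list alone (median 2.81, adjusted p = 0.000726, and adjusted p = 0.372 with an estimated correlation). Of 29 glutathione S-transferases 15 were higher and 2 lower, also when adjusted over the list alone (median 0.47, adjusted p = 0.00158, and adjusted p = 0.372 with an estimated correlation). Of 5 ethylene genes 4 were higher, also when adjusted over the list alone (median 0.56, adjusted p = 0.0115, and adjusted p = 0.272 with an estimated correlation). Photosynthesis and plastid genes by symbol were lower in 19 of 36 and higher in 4 (median -0.32, adjusted p = 0.00668, and adjusted p = 0.510 with an estimated correlation). The 4 reference genes had a median of -0.32 as well. ELIP was lower by -1.36, and the light-harvesting genes CAB3 and LHCP by -0.28 and -0.38; CAB3 lost its call in 5 of 18 alternatives (adjusted p up to 0.289), under cyclic loess, with the replicate block, and without variegated array 1 or 3 or stunted array 3. HO3, for a haem oxygenase, was higher by 1.91 (adjusted p = 0.000911). Another 8 lists by symbol were called upward in this comparison, none of them with an estimated correlation.

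In total 12257 probe sets (39.6%) differed between stunted and variegated plants, 5512 higher and 6745 lower in stunted plants, and 2739 by at least 2-fold. Higher probe sets outnumbered lower ones under cyclic loess (6543 and 5673). Without stunted array 3 the count was 8129. Among probe sets without a gene, the rule named a probe set at background in variegated plants that was at least 22.5-fold higher, a difference of 5.57 upward, and differences of -4.67 and -4.44.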

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

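The tests of RNA quality, of background through pathogen probe sets, of a shift that depends on level and of the shared wild type arrays were chosen after the result was seen, as were the covariate for the ribosomal RNA score and the fit without 3 arrays. For RNA quality, the requirement of at least 4 measured transcripts was also set after the values were seen.

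Genes that rose in variegated plants and differed between the classes by the direct test of stunted against variegated plants were mostly higher in stunted plants. The differences were 0.82 and 0.54 for the 2 probe sets of AOX1, 0.89 for CYP82A3, 1.01 for GSTU21, 2.89 for GSTU42, 0.61 for NOD33, 0.54 for VSP27, 0.75 for SMEP1, 1.44 for WRKY19, 1.87 for WRKY57, 0.71 for MYB175 and 0.50 for MYB176. They were -0.93 for HSP23.9, -1.13 for BMY1 and -0.89 for MYB138. Among genes that fell in variegated plants they were 0.50 for IF7GT, -0.43 for PHR18 and -0.27 for BCH3. The difference for VSP27 was lost in 9 of 18 alternatives (adjusted p up to 0.142), with each array left out except wild type arrays 1 and 3 and with the ribosomal RNA covariate. That for HSP23.9 was lost in 9 (up to 0.156), with cyclic loess, the ribosomal RNA covariate, any variegated array left out, wild type array 1 or 3, or stunted array 2 or 3. That for NOD33 was lost in 4 (up to 0.103), without variegated array 1 or 2 or stunted array 2 or 3. In all, 12257 probe sets and 13 gene lists differed between the classes, none of the lists with an estimated correlation. The 534 shared probe sets included 216 that differed, 194 of them changed more in stunted plants. Another 27 were called in opposite directions against wild type, 21 of which rose in variegated and fell in stunted plants. The 3 probe sets of LOC100306345, chosen after their values were seen, are among those 21.

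In stunted against wild type plants 53.6% of the probe sets tested were called, 16599 of 30981. A shift between arrays that depends on level and was left after RMA is argued against as the whole cause. Cyclic loess turned the balance of rises and falls and gave 16474 calls, 15327 of them among the 16599. That test is weak, since RMA had already equalised the arrays, whose deciles differed by at most 0.157. A similar count was thus likely beforehand. Background is argued against too, since 0.120% of the pathogen probe sets were called (28 of 23350). These were adjusted apart from the soybean probe sets, which made their cut-off stricter. At an unadjusted limma p under 0.05 there were 1582 of 23350 pathogen and 18482 of 30981 soybean probe sets. The authors' normalization stays open: in each of 10 bins of mean level at least 32.8% of the calls went in the rarer direction, but RMA equalises the arrays and so balances rises and falls itself. RNA quality stays open, since 3 measured control transcripts are too few: the 3' minus 5' signal of 1, actin, was higher on every stunted array than on every wild type array, by 0.308, while it differed by -0.312 for glutathione transferase, lower on every stunted array, and by -0.399 for P450. The difference in growth named by the groups is an open, untested explanation.

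Calls in variegated plants leaned the same way in stunted plants, 534 of 682. Wild type arrays shared by both comparisons are argued against as the whole cause, since with separate wild type arrays the covariance stayed positive in all 6 ways. The lowest was 0.0306, beside at most 0.0120 in simulations with shared arrays and no difference. It ranged up to 0.127 with the choice of wild type pair, so the simulations do not hold the variation between wild type arrays and set no firm limit. Variation of that kind, common to many probe sets, is not excluded. Carrying the RNA interference construct is common to both classes and stays an open, untested explanation. The shared count was 341 without wild type array 2, 335 without stunted array 2, and 221, 167 and 194 without variegated arrays 1, 2 and 3.

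Wild type arrays 1 and 3 and stunted array 1 stood apart on the ribosomal RNA score, at -2.42, -3.19 and -3.53 against -0.19 to 1.77 on the others. A labelling or RNA batch that follows this score is argued against as the whole cause of the calls in variegated plants. With the score as a covariate, fold changes of called probe sets had a slope of 0.993 on those without it in variegated and 1.01 in stunted plants. Wild type and stunted plants both held low and high scores, so the covariate could move stunted fold changes little. The slope in stunted plants was thus near certain beforehand and decides nothing. With the covariate 491 probe sets were called in variegated plants, 429 of them among the 682, and 11 of 31 named results lost their call. Without the 3 arrays 227 probe sets were called in variegated and 13453 in stunted plants, from fewer arrays. The 3 arrays include no variegated and a single stunted plant, so no comparison within them can be made, and no biological explanation was tested.

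Other splits of the arrays into groups of the same sizes were fitted in the same way. For variegated against wild type, 1 of 35 splits, the real one, gave as many calls (682, highest other 243), a share under 0.05. For stunted against wild type it was also 1 of 35 (16599, highest other 8984). That other split set wild type arrays 1, 2 and 3 against wild type array 4 with the stunted arrays, and so kept most of the real grouping. A share of 1 in 35 is the smallest these splits allow, so chance is made less likely but is not excluded. Most other splits in both comparisons mixed the groups, which widens the spread within them. For stunted against variegated, 10 splits are too few for a share under 0.05 (12257, highest other 0). For calls shared by both classes 1 of 100 drawn splits gave as many (534, highest other 0). The other splits mixed the stunted with the other arrays, which widens the spread within groups, so this count says nothing on the sharing itself. For the number of gene lists called, 26 of 100 drawn splits gave as many (29, highest other 36), so chance cannot be excluded for that number.

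One wild type array stood far from the other 3, past the 95% critical value of Dixon's ratio, for 9 of 131 probe sets and array measures tested; chance gives about 1 in 20. The ratios were 0.906 and 0.895 for 2 probe sets of BCH3, 0.974 for BZIP105, 0.847 for CYP74A1, 0.931 for KTI-2, 0.973 for a probe set of MYB92, 0.849 for PCNA, 0.916 for PHR18 and 0.892 for SUT1. Groups of 3 arrays were not tested.

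Among probe sets designed on the 2 pathogens, 20 rose and 8 fell in stunted against wild type plants. Of these 28, 18 exceeded 5 on the log2 scale, also in wild type plants, against 0.681% of all pathogen probe sets. Whether they read soybean or pathogen transcripts was not tested. The largest fall was -1.50 and the largest rise 4.40, from 5.37 in wild type and 6.37 in variegated to 9.77 in stunted plants. In stunted against variegated plants 11 rose and 1 fell. In variegated against wild type plants limma called 0 of them, with 1382 at an unadjusted p under 0.05.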

How the results depend on the processing

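The tests with a ribosomal RNA or actin covariate and without 3 arrays were chosen after the data were seen. No named gene or list changed sign past the threshold, but the balance of rises and falls turned in stunted against wild type under cyclic loess (8640 rose, 7834 fell) and scaling to the pathogen probe sets (8068, 7751), and in stunted against variegated under cyclic loess (6543, 5673). Calls in variegated against wild type plants numbered 1040 with array weights, 430 with only the groups compared, 197 at a fold change of at least 2, 169 at an adjusted p under 0.01, 198 with 1 probe set per gene and 227 without the 3 arrays low on the ribosomal RNA score. Leaving out single arrays gave 195 to 912: 450 without wild type array 2, 416 without stunted array 2, and 245, 195 and 225 without variegated arrays 1, 2 and 3. Shared calls under the same settings numbered 806, 340, 143, 148, 161 and 201, and 167 to 758 with single arrays left out: 341 without wild type array 2, 335 without stunted array 2, and 221, 167 and 194 without variegated arrays 1, 2 and 3. Stunted against wild type gave 3510 at a fold change of at least 2, 3441 with 1 probe set per gene and 12694 to 17032 with arrays left out. Stunted against variegated gave 2739, 6673 at an adjusted p under 0.01, 2727 with 1 probe set per gene, and 8129 to 12806 with arrays left out, the lowest without stunted array 3. A fold minimum, a stricter p and a single probe set per gene lower a count by construction; for array weights, the groups compared and arrays left out the cause was not tested.

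With the replicate number as a replicate block, variegated against wild type gave 305 calls, stunted against wild type 15510, stunted against variegated 10787 and the overlap 270. The numbers do not pair the arrays: residuals of arrays with the same number correlated at -0.428 to 0.111 over 9 pairs. Those with different numbers correlated at -0.200 to 0.464 over 18 pairs, the highest between wild type array 2 and variegated array 1. Variation shared by arrays of different groups under other numbers is therefore not excluded. Lists called numbered 29, and 27 to 38 in the other settings except with an estimated correlation, where camera called 0; fry called 3, 21 and 19 in the 3 comparisons, in the order above of variegated and stunted against wild type and stunted against variegated. With the actin signal as covariate, which differs between stunted and wild type plants, counts were 531, 11679 and 8351 and the overlap 379. Other settings stayed within 1.5 times of each count. Of 31 named results in variegated plants, 7 to 27 were called with an array left out; in stunted plants 98 to 107 of 107; in stunted against variegated plants 76 to 97, where 98 were called, the lowest without stunted array 3. Signal over background limits the probe sets tested to 30981.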

Other observations

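Of the tests below, those of the lists by symbol were chosen after the gene symbols and the arrays had been seen, and before any groups were compared.

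Sugar transport and phosphate genes moved in both directions in stunted plants. Among sugar transporters and carbohydrate enzymes by symbol, 7 of 16 rose and 5 fell, at a median of 0.19 (adjusted p = 0.417); STP1 rose by 1.18 and SWEET31 by 1.28, while SWEET24 fell by 1.45, a call lost without stunted array 2 or 3 (adjusted p up to 0.0661). Of 21 phosphate starvation genes 3 rose and 6 fell: DGD1 rose by 0.70, and PHR18 and PHR35 fell by 0.90 and 0.81. Plasma membrane aquaporins had 5 of 14 fall and 1 rise: PIP1-6 fell by 0.83, and PIP2-6 rose by 0.75 (median -0.19, adjusted p = 0.8). Of 8 sieve element occlusion genes 3 rose and 3 fell, with a median of -0.05 and a mean of 0.00488 (adjusted p = 0.869), while the direction given by camera was upward. Of 11 seed maturation genes 4 rose and 2 fell, PM9 by 1.06 and PM29 by -1.13; the PM29 call was lost in 8 of 18 alternatives, among them without wild type array 1 or 4 or any stunted array (adjusted p up to 0.113).

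Jasmonate genes moved in both directions in stunted plants. Of the 8 genes of the list fixed beforehand 5 rose and none fell, and 5 rose and 1 fell when adjusted over the list alone, with a median of 0.44 (adjusted p = 0.116). VSP27 rose by 1.66 and LOX1.4 by 0.63. In the list by symbol 5 of 14 rose, among them AOS2 by 0.62, and 4 fell, among them CYP74A1 by -1.75 and AOC3 by -1.71. The median of that list was -0.12 (adjusted p = 0.959). Of 7 heat shock genes fixed beforehand 3 fell and none rose, also when adjusted over the list alone (median -0.35, adjusted p = 0.336); HSP90A1 fell by 0.91 (adjusted p = 0.0111), a call lost without stunted array 3, and HSP90-1 fell by 0.59. The heat shock factor gene HSF-01 rose by 1.54. Of 5 antioxidant enzyme genes CAT1 rose by 0.42 and CAT5 fell by 0.38. The CAT5 call was lost with only the groups compared and without wild type array 1 or 3 or stunted array 2 or 3 (adjusted p up to 0.114). By symbol DHAR3 fell by 0.83 and ALDH3J2 by 1.97. Of 52 MYB genes 15 rose and 10 fell (median 0.04, adjusted p = 0.133). MYB29, at background in wild type, was at least 5.08-fold higher, and MYB127 fell by 1.81.

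Hormone genes by symbol had 7 of 20 rise and 2 fall in stunted plants, at a median of 0.24 (adjusted p = 0.0528). BEHL1 rose by 0.90, GAI1 by 0.57, and GA20OX3, for a gibberellin oxidase, fell by 1.02. PCNA, the replication clamp, fell by 0.78.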
